A study of Mus musculus with 4 samples.

How the data were processed

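Single cells from the cochleae of 4 wild-type mice were profiled by droplet RNA sequencing. Per the labels, the animals were males of the inbred CBA/CaJ strain aged 9 weeks, and 8 cochlear capsules were opened. The modiolus, the bony core that houses the spiral ganglion, was microdissected together with spiral limbus, the inner sulcus, some outer sulcus and pieces of the organ of Corti. Tissue of each mouse was kept as its own pool, digested with collagenase IV and then papain for 30 min each at 37 °C, and captured 2.5 h after the animal was killed. The v2 chemistry of 10x Genomics tags each captured polyadenylated molecule near its 3′ end with a cell barcode and a unique molecular identifier (UMI), so PCR copies are collapsed and a count is a number of captured molecules.

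The deposited tables hold raw UMI counts per gene symbol and cell, with 1 table per mouse. Cell Ranger 2.0.1, Seurat 1.4 and the mouse build mm10 (GRCm38) are named in the submitters' processing notes, and the filters on cells and genes are not given in the sources used here. A combined table of the same raw counts was compared with the tables per mouse cell by cell and held the same values. A deposited normalized table on a natural log scale was not used here. The authors' deposited cell annotation gives each cell a class (type I, type II or putative spiral ganglion neuron) and each type I cell a subtype (IA, IB or IC). It was used as it stands, with no clustering. No cell carries a non-neuronal label, so the comparison of neurons with non-neuronal cells was not run. How the authors assigned the labels is not given in the sources used here. The labels describe the same cells whose UMIs are compared, so genes that separate the populations are not independent findings.

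The files held 6713 cells and 18143 genes, of which 77 had no UMI. UMIs were summed per mouse and population, which gave 20 sums, each of at least 10 cells. A mouse is the replicate throughout, and cells are not counted as replicates. The sums were fitted in 1 model with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood test), with the mouse as a block. The low-count filter left 13005 genes. Residual degrees of freedom were 12, the median prior degrees of freedom 66.8 and the biological coefficient of variation 0.0486. Type II was compared with the unweighted mean of types IA, IB and IC, each type I subtype with the unweighted mean of the other subtypes, and putative neurons with the unweighted mean of all other populations. Benjamini-Hochberg adjusted p under 0.05 was the threshold within each comparison. Log2 differences are edgeR estimates, with a standard error (SE) taken from the estimate and its F statistic. Directions in single mice come from log2 CPM with a prior count of 2. Levels are a gene's UMIs relative to all UMIs of its sum, in CPM, as mean ± SD over the 4 mice. All p-values are two-sided.

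Function lists of genes were written before the data were examined. They cover potassium channels, sodium channels, calcium channels, HCN and TRP channels, glutamate receptors, inhibitory and cholinergic receptors, monoamine and peptide receptors, calcium-binding proteins, neuropeptides and granins, transmitter synthesis and transport, synaptic vesicle and release, axon guidance, cell adhesion, transcription factors, neurotrophic signalling, axonal cytoskeleton, oxidative phosphorylation, mitochondrially encoded genes, immediate early and dissociation genes, axonal injury response and glial transcripts. Each of the 21 lists was tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. The test was repeated with a correlation estimated from each list. Fry was run as well, which tests a list against no change and not against other genes. Genes named in the text follow a rule set before the data were examined. From each comparison it takes the 10 highest and 10 lowest log2 differences among genes past the threshold with at least 20 UMIs in the higher population and the same direction in every mouse. Unnamed Gm and Rik models are skipped, and some genes that the rule names are not reported here. From each list it takes up to 4 members with the largest differences. Neuron type markers of each fixed marker list are given as counts, and sums over markers of other cell types were computed for each population. The comparisons, tests, lists and thresholds, like the alternatives except those named as added, were also set before the data were examined.

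For shares of cells with a UMI of a marker, each cell was thinned to 4215 UMIs, the depth at percentile 10 over all cells, and shallower cells were left out. This removed 205 type IA, 98 type IB, 126 type IC, 5 type II and 237 putative cells. Differences between populations were tested by an exact two-sided sign-flip permutation over the mice, whose 16 arrangements allow no p below 0.13, so no such test can pass the threshold. Shares of populations within a mouse carry exact 95% binomial intervals (Clopper-Pearson). Intervals, and limits set by 3 counts where a count is 0, cover counting error only.

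Doublets were called per mouse with Scrublet in Scanpy 1.11.5 (expected rate 0.06, score threshold 0.25, seed 1). It called 204 of the 6713 cells (3.04%), which stayed in the sums and were left out in an alternative. The pairing of sums within a mouse comes from their origin in the same animal. It was checked by correlating deviations from the population means over 4804 genes. Within a mouse r lay between 0.525 and 0.646 for pairs of type I subtypes, and between 0.0849 and 0.646 over all pairs. The model was tested on simulated data drawn from the real means, library sizes and dispersions, with genes changed 1.5-fold, 2-fold or 4-fold in 1 population. Run on 12540 to 12568 genes, it recovered of the 67 genes changed 2-fold 55.2% for type II, 88.1% for type IA, 92.5% for type IB, 94.0% for type IC and 76.1% for putative neurons. Of the unchanged genes 0.0548% to 0.13% were called.

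Alternatives were DESeq2 size factors, DESeq2 1.42.0 as the tool, no low-count filter, no mouse block, each mouse left out, doublets left out, the same number of cells in every sum of a mouse, cells above the median depth, and labels rebuilt from a part of the UMIs. For the last, each cell's UMIs were split at random with a share of 0.5, a logistic model (C 0.001, 2000 variable genes, scikit-learn 1.9.0) was trained on the authors' labels in the other mice with 1 part, and its labels were used to sum the other part. It gave 89.6% of cells their deposited label, from 52.5% of putative to 97.1% of type IA cells. Alternatives added after seeing the data left out cells with 3 or more Fabp7 UMIs (sums of at least 5 cells), left out type II cells lacking a Prph UMI, or compared putative neurons with type I alone. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, AnnData 0.12.19 and Matplotlib 3.10.9 were also used. Gene coordinates were looked up by symbol in the GENCODE vM21 annotation of GRCm38.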

Results

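The spiral ganglion holds the neurons that carry signals from the hair cells of the cochlea to the brainstem. Most are myelinated type I neurons, which contact inner hair cells, and a small unmyelinated group, the type II neurons, contacts outer hair cells. The series was made to describe the native neuron types of the adult mouse cochlea, and the question put to the data here is which genes and gene groups set each annotated population apart from the others. UMI counts of 6713 annotated neurons from 4 mice were analysed. Mouse 1 gave 1238 cells with 20621487 UMIs, mouse 2 gave 2232 cells with 27309045, mouse 3 gave 1720 with 23490275 and mouse 4 gave 1523 with 15151343. Median UMIs per cell in mice 1 to 4 were 17834, 13242, 14616 and 10072. The most abundant transcript in every library was the mitochondrially encoded mt-Co3, at 2.35% to 2.67% of UMIs.

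Type I neurons made up most of the annotated cells in each mouse, with 2384 cells of type IA, 1625 of type IB and 2104 of type IC. Type IA took 35.3% ± 1.21 of the cells (SD, n = 4 mice), type IB 24.4% ± 0.985 and type IC 31.5% ± 1.22. These SDs were 1.02, 0.921 and 1.05 times those that binomial sampling gives. Type II neurons, 95 cells in all, took 1.504% ± 0.589, and the 505 cells that the authors call putative spiral ganglion neurons took 7.34% ± 2.04. Both varied more between mice than sampling gives, by 2.00 and 3.10 times. The type II share ran from 0.672% in mouse 2 (exact 95% interval 0.377% to 1.11%) to 1.98% in mouse 3 (1.37% to 2.75%). Putative neurons ran from 4.68% in mouse 1 (3.58% to 6.01%) to 9.52% in mouse 4 (8.09% to 11.1%). Depth differed between populations, with a median of 5647 ± 2340 UMIs per cell in putative neurons against 12385 ± 5888 in type II, 13166 ± 3409 in type IA, 14541 in type IB and 15802 in type IC (means over mice).

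**Figure D1:**
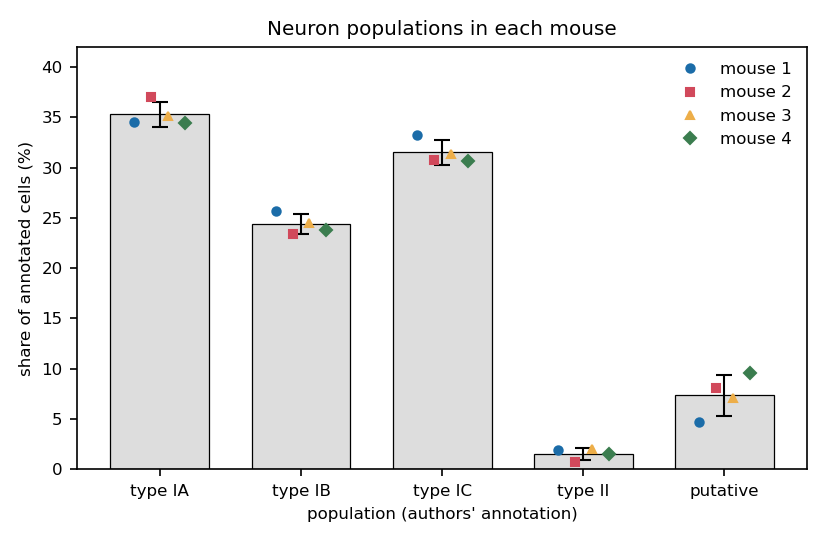
Share of each annotated population among the neurons of a mouse, in percent. Bars are means over 4 mice, error bars the SD, and points the mice, with type II lowest at 1.504% and type IA highest at 35.3%.

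Genes are identified by symbol, and the UMIs lie near the 3′ ends of transcripts with no position given within a gene. The protein-coding genes that the comparisons lean on most lie in GRCm38 as follows. Calb2 is on chromosome 8 (110137502 to 110168210, minus strand), Calb1 on 4 (15881264 to 15908064, plus), Lypd1 on 1 (125867622 to 125913101, minus) and Pou4f1 on 14 (104461676 to 104467999, minus). Slc17a6 is on chromosome 7 (51622006 to 51671119, plus), Prph on 15 (99055174 to 99058978, plus), Dupd1 on 14 (21676537 to 21714576, minus) and Myl1 on 1 (66924295 to 66945404, minus). Th lies on chromosome 7 (142892752 to 142931128, minus), Npy on 6 (49822710 to 49829507, plus), Fabp7 on 10 (57784881 to 57788450, plus), Apoe on 7 (19696109 to 19699188, minus) and Fosb on 7 (19302696 to 19310051, minus).

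Type II neurons differed from type I first by genes that were close to absent or, like Myl1, far lower in type I. Prph encodes peripherin, the intermediate filament long used to recognise type II neurons, and it stood at 475 ± 306 CPM (SD, n = 4) in type II and 1.03 to 1.251 CPM in the type I subtypes, 365-fold higher (log2 difference 8.51 ± 0.17, SE). Of its UMIs in type II 20.7% lay in 1 cell of mouse 4, the mouse with the highest level (895 CPM). Dupd1, a dual-specificity phosphatase gene, reached 1197 ± 452 CPM against 1.71 to 2.60 (8.96 ± 0.21). Myl1, a myosin light chain best known from fast skeletal muscle, reached 5185 ± 1898 CPM against 10.3 to 44.4 (8.09 ± 0.16), and Th, the rate-limiting enzyme of catecholamine synthesis, 112 ± 54.0 CPM (8.06 ± 0.31). Fstl5, Edaradd, the calcium-activated chloride channel gene Ano2, the BMP antagonist gene Nog and Cilp were higher by 7.97 to 8.34 on the log2 scale. Slc6a4, the serotonin transporter, had 20 UMIs in type II (18.9 ± 8.73 CPM) and 3 in type I.

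Genes of transmission and excitability separated the types in both directions. Of the 45 synaptic vesicle and release genes tested, 13 were higher in type II, among them Syt1 (6.17 ± 0.25), and 20 were lower, among them Snap25 (-0.95 ± 0.10). The vesicular glutamate transporter genes went apart, with Slc17a6 higher (1.16 ± 0.12) and Slc17a7 lower (-1.68 ± 0.18). The difference of Slc17a6 rests mainly on type IA, at 18.4 to 21.0 CPM per mouse. Type II stood at 123 to 228 CPM, type IB at 146 to 170 and type IC at 178 to 222. Of 40 potassium channel genes 10 were higher, led by Kcnc4 (7.47 ± 0.34), and 14 lower. Among 12 sodium channel genes 7 were higher, among them Scn9a (5.74 ± 0.27), and 4 lower, including Scn4b (-1.65 ± 0.15). Neuropeptide and granin genes Scg2 (7.09 ± 0.37) and Calca (6.47 ± 0.48) were higher as part of 6 of 13, with 3 lower. With all type II cells none of these lists passed camera (adjusted p = 0.0635 to 0.866). Of the fixed type II markers 6 of 7 tested were higher, and of the type I markers 6 of 7 were lower and none higher.

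Transcripts of the respiratory chain fell in type II. Of 76 oxidative phosphorylation genes 70 were lower and none higher (70 when adjusted over the list alone; median log2 difference -0.53), with Cox5a at -1.24 ± 0.10 and Ndufs1 at -0.88 ± 0.14. Camera called the list with adjusted p = 5.35e-47, but adjusted p = 0.0621 with an estimated correlation. Of 13 mitochondrially encoded genes 11 were lower (11 adjusted over the list alone), such as mt-Nd3 (-0.80 ± 0.10), and the call at adjusted p = 6.05e-10 was lost with an estimated correlation (adjusted p = 0.116). The axonal injury response list rose, with 8 of 11 genes higher and 1 lower, the same numbers adjusted over the list alone (adjusted p = 1.58e-10, and 0.0474 with an estimated correlation). It includes Gap43 (4.52 ± 0.51), a growth cone protein, and Tubb2b (2.55 ± 0.24), a tubulin. Immediate early and dissociation genes were higher in 20 of 32 cases and lower in none (23 and 1 adjusted over the list alone), with Dusp1 at 1.36 ± 0.10 and Btg2 at 1.20 ± 0.16 (camera adjusted p = 1.05e-12, and adjusted p = 0.0604 with an estimated correlation).

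Transcription factor genes were higher in type II in 24 of 65 cases and lower in 8 (26 and 9 adjusted over the list alone; camera adjusted p = 0.000323, and adjusted p = 0.0621 with an estimated correlation). Gata3, a regulator of inner ear development, was higher by 2.98 ± 0.12, and Prox1, a homeobox gene, lower (-2.85 ± 0.28). Neurotrophic signalling genes were higher in 7 of 21 cases and lower in 2, the same numbers adjusted over the list alone. They include the neurotrophin gene Bdnf (5.21 ± 0.54), the GDNF receptor gene Gfra1 (2.71 ± 0.25) and Ngfr (2.09 ± 0.09), and the list's camera call at adjusted p = 0.00439 was lost with an estimated correlation (adjusted p = 0.0786). The 10 genes ranked lowest had no UMI in the 1288798 UMIs of type II. A floor of 3 counts over that total puts Col19a1 at least 3.14-fold and Xlr3a at least 2.81-fold lower, and Lrrc52, Spdya, Tecta, Zswim3, Zfp958, Ccdc30, Cyp4x1os and Inadl at least 1.44-fold to 2.48-fold lower. The calls of the last 8 ended without mouse 1 (adjusted p = 0.0668 to 0.149) or without mouse 3 (0.0508 to 0.0986).

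Apart from genes given by UMIs, each gene with a log2 difference here and below moved the same way in 4 of 4 mice. By edgeR's quasi-likelihood test 3088 of 13005 genes differed between type II and type I, 1560 higher (50.5%) and 1528 lower, and 1318 of them by at least 2-fold. With DESeq2 61.9% of the calls were higher. Markers of satellite glia, the cells that wrap ganglion neurons, moved with this comparison. Their sum was 8658 ± 2075 CPM in type II against 1268 to 1349 in type I, Apoe was higher by 2.88 ± 0.08 and Fabp7 by 5.29 ± 0.28, and 39.6% ± 15.0 of type II cells held 3 or more Fabp7 UMIs. Without such cells, an alternative added after seeing the data, 1914 genes were called, Fabp7 stood at 0.14, Apoe at 0.07 and the neuropeptide gene Npy at 0.11 (6.37 ± 0.30 with all cells). Camera then called sodium channels (adjusted p = 0.00585, and 0.0323 with an estimated correlation) and cell adhesion (0.011, and 0.211 with an estimated correlation), both up. With an estimated correlation, oxidative phosphorylation, neurotrophic signalling and axonal injury response (each 0.0323) and immediate early and dissociation genes (0.0291) then held. Mitochondrially encoded genes (0.123) and transcription factors (0.0688) did not. The list of glial transcripts itself, with 3 of 19 genes higher and 4 lower, was not called (adjusted p = 0.239). Of the 95 type II cells 58 had a Prph UMI. They held 145092 of the 546679 type II UMIs in mouse 1 and 81652 of 131668 in mouse 2. In mouse 3 they held 215684 of 390376 and in mouse 4 159489 of 220075. The values with all cells thus rest in large part on the other 37 cells, which had no Prph UMI. With these left out, also added after seeing the data, 3887 genes were called, Snap25 stood at -2.02, Slc17a7 at -3.70, Gata3 at 3.64 and Slc17a6 at 0.47 (1.16 with all cells), and the neurotrophic list was no longer called (adjusted p = 0.341). Camera then called synaptic vesicle and release (adjusted p = 1.92e-06), potassium channels (0.0188) and calcium-binding proteins (0.0322), all down, and with an estimated correlation adjusted p was 0.071, 0.234 and 0.264. Immediate early and dissociation genes (adjusted p = 0.0172 with an estimated correlation) and the mitochondrially encoded and oxidative phosphorylation lists (both 0.0214) then held, while sodium channels (adjusted p = 0.932) and cell adhesion (0.607) were not called. Cells above the median depth gave 1659 calls, in a fit that also lacked the type II sum of mouse 2 (7 cells), and the same number of cells in every sum 1563. With labels rebuilt from a part of the UMIs 36.5% of 2650 calls were higher, and Slc17a6 stood at -0.12.

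Type IA neurons were marked by calretinin. Calb2, which encodes this calcium buffer, stood at 9866 ± 844 CPM (SD, n = 4) in type IA, 2458 ± 287 in type IB and 719 ± 116 in type IC, a log2 difference of 2.92 ± 0.28 from the mean of the other subtypes (adjusted p = 2.7e-06, higher in 4 of 4 mice). Higher still in ratio were the formin gene Fmnl1 (4.23 ± 0.22), Tmem132c (4.16 ± 0.11), the cilia gene Hydin (3.94 ± 0.19), B3gat1, which makes the HNK-1 carbohydrate (3.61 ± 0.11), and Myoz1 (3.45 ± 0.39). Cacna1b, the pore of N-type calcium channels (3.24 ± 0.15), the protocadherin gene Pcdh20 (3.13 ± 0.08), Mapk4 (3.09 ± 0.19) and Naip5 (3.01 ± 0.26) followed, as did Rxrg, a retinoid receptor (2.77 ± 0.08). All 4 fixed type IA markers were higher. In the other direction stood Slc17a6, at 19.8 ± 1.10 CPM in type IA against 160 ± 11.7 and 207 ± 19.7 (-3.16 ± 0.07), and the transcription factor genes Pou4f1 (-3.13 ± 0.10) and Runx1 (-2.73 ± 0.08). Khdrbs2, Mgat4c, Ryr3, a ryanodine receptor, Ntng1, a netrin relative, Hmcn1, Tenm2 and Edn2 were lower by 3.25 to 3.85 on the log2 scale, and Rgs20 had 3 UMIs in type IA and 112 in the others.

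Potassium channel genes were lower in type IA in 17 of 40 cases and higher in 8 (18 and 9 adjusted over the list alone). Kcnd2, an A-type channel, stood at -3.90 ± 0.21 and Kcnj9 at -2.92 ± 0.23. The camera call (adjusted p = 0.00469) was lost with an estimated correlation (adjusted p = 0.196). Axon guidance genes were lower in 19 of 49 cases and higher in 7 (20 and 7 adjusted over the list alone), with the semaphorin gene Sema3a at -2.90 ± 0.17 (camera adjusted p = 0.00292, and adjusted p = 0.122 with an estimated correlation). Neuropeptide and granin genes were lower in 7 of 13 cases and higher in 1, the same numbers adjusted over the list alone. The prohormone convertase gene Pcsk2 stood at -2.32 ± 0.12 and Chgb at -0.68 ± 0.06 (camera adjusted p = 0.000723, and adjusted p = 0.122 with an estimated correlation). Apart from Calb2, 2 calcium-binding protein genes were higher and 12 of the 25 lower, also adjusted over the list alone, including Calb1 (-2.14 ± 0.11) and Ncald (-1.81 ± 0.23). That list's call at adjusted p = 0.0364 gave adjusted p = 0.196 with an estimated correlation. Mitochondrially encoded genes were higher in 12 of 13 cases (13 adjusted over the list alone; median 0.33, camera adjusted p = 0.000145), and with an estimated correlation adjusted p = 0.356. Mitochondrial UMIs took a median of 10.3% ± 0.758 per type IA cell, 8.95% ± 0.519 in type IB and 7.15% ± 0.287 in type IC.

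In total edgeR called 3709 genes in type IA, 1846 higher and 1863 lower, 390 of them by at least 2-fold. Without the mouse block 2071 were called, and with the same number of cells in every sum 176. The mitochondrial genes mt-Nd1 (0.51 ± 0.11) and mt-Atp6 (0.38 ± 0.11) were not called without mouse 1 (adjusted p = 0.0805) and without mouse 3 (adjusted p = 0.0567).

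Type IB neurons were set apart by fewer genes, led by the giant muscle protein gene Ttn and by Calb1, which encodes the calcium buffer calbindin. Ttn stood at 74.8 ± 10.5 CPM in type IB against 3.85 in type IA and 5.10 in type IC (log2 difference 4.06 ± 0.10), and Calb1 at 66.6 ± 5.49 CPM against 5.52 ± 1.30 and 9.07 ± 2.08 (3.24 ± 0.08). Lrrc52, a subunit of large-conductance potassium channels, was higher by 2.40 ± 0.16, Dpp10, an auxiliary subunit of A-type channels, by 2.99 ± 0.26, and Kcnd2, their pore, by 2.56 ± 0.15. Rasd2 (1.84 ± 0.24) and Lypd6 (1.73 ± 0.13) were higher too. Ryr3 and Ntng1, each higher by 1.51, stood higher still in type IC, since type IB is compared with the mean of the other subtypes. Kcnc2 (-3.26 ± 0.30), the anchoring protein gene Sphkap (-2.01 ± 0.12), Tmem132c (-1.82 ± 0.21), Chst9 (-1.82 ± 0.38), Slc15a5 (-1.77 ± 0.17) and the adrenergic receptor gene Adrb1 (-1.75 ± 0.35) were lower, as were the type IC markers Lypd1 (-1.51 ± 0.24) and Grm8 (-1.29 ± 0.18). Of these Tmem132c stood lower still in type IC, and Chst9, Lypd1 and Grm8 lower still in type IA. Ndst4 had no UMI in the 21631826 UMIs of type IB, at least 7.05-fold lower by a floor of 3 counts.

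Axon guidance genes rose in type IB, with 12 of 49 higher and 2 lower (15 and 4 adjusted over the list alone), and this call held with an estimated correlation (adjusted p = 1.05e-06, and 0.0071 with an estimated correlation). In type IC 16 were higher and 11 lower, and the list was not called (camera adjusted p = 0.217). Its mean was 0.22 in type IC against 0.19 in type IB, and its median 0.02 against 0.13. Type IA, where the list was low (mean -0.41), enters the mean that type IB is compared with. In type IB Sema3a (1.13 ± 0.14, and higher still in type IC) and Sema3e (0.91 ± 0.05) were higher and the semaphorin receptor gene Nrp1 lower (-0.96 ± 0.10). Genes of transmitter synthesis and transport rose in 4 of 16 cases and fell in none, the same numbers adjusted over the list alone, with Slc17a6 (1.31 ± 0.05, and higher still in type IC) and Slc6a17 (0.41 ± 0.06) among them (adjusted p = 4.11e-06, and 0.019 with an estimated correlation). One gene of that list had no UMI in type IB, and at its bound the list mean of 0.04 becomes 0.13. Potassium channel genes were higher in 11 of 40 cases and lower in 3 (15 and 7 adjusted over the list alone), including Kcnk10 (1.42 ± 0.24), with camera adjusted p = 0.00638, and adjusted p = 0.254 with an estimated correlation. Calcium-binding protein genes were higher in 2 of 25 cases, Calb1 and S100a10 (0.31 ± 0.06), and lower in 1, Hpcal1 (-0.60 ± 0.11), or 3 and 2 adjusted over the list alone. Their camera call at adjusted p = 0.0362 was lost with an estimated correlation (adjusted p = 0.254). The transcription factor genes Runx1 (1.29 ± 0.07, and higher still in type IC) and Casz1 (1.03 ± 0.07) were higher and Ebf1 lower (-0.81 ± 0.05), as part of 7 higher and 4 lower of 65, a list not called (adjusted p = 0.406).

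By edgeR 823 genes differed in type IB, 492 higher and 331 lower, 85 of them by at least 2-fold. Called doublets were most common in type IB, at 6.80% of its cells and 10.9% in mouse 2, and leaving doublets out gave 794 genes. The count was 333 without the mouse block, 506 without mouse 3, 502 in cells above the median depth and 23 with the same number of cells in every sum. Of the 10 genes ranked lowest, Ndst4 lost its call without mouse 2 (adjusted p = 0.311), BC030500 (-2.37) without mouse 2 or mouse 3 (adjusted p = 0.235 and 0.202), and Grxcr2 (-1.72) without mouse 1, mouse 2 or mouse 3 (adjusted p = 0.0880 to 0.121). With doublets left out BC030500 (-1.86, adjusted p = 0.202) and Grxcr2 (-1.61, adjusted p = 0.0544) were not called either.

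Type IC neurons carried high levels of Lypd1, a membrane-anchored modulator of acetylcholine receptors. It stood at 2953 ± 225 CPM (SD, n = 4) in type IC, 110 ± 22.5 in type IA and 200.1 ± 35.3 in type IB (log2 difference 4.31 ± 0.22). Pou4f1, a POU-domain factor of sensory neurons, reached 167 ± 7.47 CPM against 8.03 ± 0.521 and 30.7 ± 1.82 (3.38 ± 0.07), and Grm8, a metabotropic glutamate receptor, 42.1 ± 3.32 CPM (3.76 ± 0.10). Higher were also BC030500 (4.98 ± 0.28), the sulfotransferase gene Chst9 (4.75 ± 0.18), Galntl6 (4.32 ± 0.47), Ccdc109b, a subunit of the mitochondrial calcium uniporter (4.05 ± 0.08), Glis1 (4.04 ± 0.19), Diras2 (4.02 ± 0.28) and Ptchd4 (3.65 ± 0.28). Ndst4 stood at 1.81 ± 0.743 CPM in type IC and 20.9 ± 14.33 in type II, against 0.151 in type IA. Lower were Naip5 (-3.35 ± 0.40), Fmnl1 (-2.97 ± 0.42), Calb2 (-2.81 ± 0.34), Ephx4 (-2.78 ± 0.13), B3gat1, Cacna1b, Cdh9, Dlgap2 and Nrxn3, the last 5 by 2.70 to 2.75 on the log2 scale. All 4 type IC markers were higher and all 4 type IA markers lower.

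Neuropeptide and granin genes were higher in type IC in 7 of 13 cases and lower in none, the same numbers adjusted over the list alone. Pcsk2 was higher by 2.37 ± 0.09, the natriuretic peptide gene Nppc by 0.70 ± 0.11 and Chgb by 0.35 ± 0.06 (camera adjusted p = 0.000512, and adjusted p = 0.247 with an estimated correlation). All 13 mitochondrially encoded genes were lower, also adjusted over the list alone (median -0.38), with mt-Nd2 at -0.45 ± 0.08 (camera adjusted p = 1.91e-06, and adjusted p = 0.308 with an estimated correlation). Nuclear genes of oxidative phosphorylation, in contrast, were higher in 4 and lower in 3 of 76 cases (adjusted p = 0.931). Potassium channel genes were higher in 16 of 40 cases and lower in 8, led by Kcnc2 (2.46 ± 0.20), Kcnj9 (2.24 ± 0.17) and Kcnk3 (1.83 ± 0.14), and this list was not called (adjusted p = 0.0541). Among HCN and TRP channel genes 6 of 17 were lower, with Hcn2 at -0.38 ± 0.05, and 1 higher (adjusted p = 0.205). Neurod1 (2.53 ± 0.25) and Runx1 (1.44 ± 0.06) were higher and Rxrg (-2.59 ± 0.12) and Casz1 (-1.60 ± 0.08) lower, among transcription factor genes of which 21 of 65 were higher and 17 lower (adjusted p = 0.641).

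EdgeR called 3389 genes in type IC, 1693 higher and 1696 lower, and 328 of them by at least 2-fold. Without the mouse block 1723 were called, and with the same number of cells in every sum 162. The call of mt-Nd1 (-0.56 ± 0.11) gave adjusted p = 0.0806 without mouse 1.

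**Figure D2:**
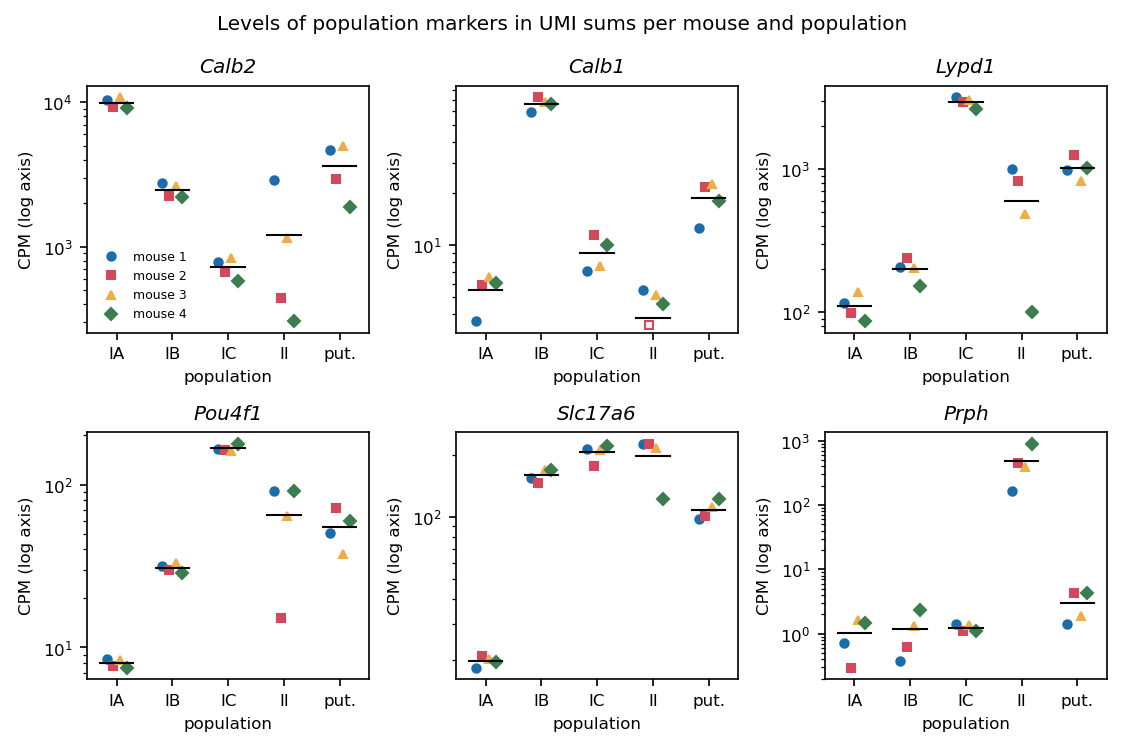
Levels of Calb2, Calb1, Lypd1, Pou4f1, Slc17a6 and Prph in each population, in CPM on a log axis. Points are the 4 mice, lines the means, and an open symbol at the edge of the axis is a sum with 0 UMIs (Calb1 in type II of mouse 2); Prph has its mean of 475 CPM in type II.

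In single cells thinned to 4215 UMIs, Prph was seen in 61.6% of type II cells and 0.283% of type I cells (difference 61.3 ± 14.2 points, SD over 4 mice), and Th in 31.5% and 0.144% (31.3 ± 12.4). Unthinned, at median depths of 12385 UMIs in type II and 13166 to 15802 in the type I subtypes, Prph was seen in 61.8% of type II cells and in 1.254%, 1.44% and 1.80% of type IA, IB and IC cells, and Th in 39.0% of type II and 0.472% of type I cells. The type I shares are what a type that should lack the gene shows. Both genes were seen together in 27.7% ± 13.1 of type II cells and in none of the thinned type I cells, where each was rarely detected. Calb1 was seen in 22.6% of type IB cells and 3.02% of the other type I cells (19.6 ± 1.77 points), or 44.1% and 7.83% unthinned. Lypd1 was seen in 98.5% of type IC cells and 36.6% of the others (61.9 ± 2.89), and Pou4f1 in 50.3% and 6.80% (43.5 ± 1.46), or unthinned in 98.6% and 66.7% and in 80.2% and 18.3%. Calb2 was seen in all thinned type IA cells and 96.1% of the others (3.95 ± 1.32), and unthinned in 99.9% and 99.1%. At 2 or more UMIs it was seen in 99.9% of type IA, 98.8% of type IB and 74.3% of type IC cells. Hbb-bs, a transcript of red cells, was seen in 77.5% to 82.2% of thinned type I cells, so a UMI in a cell does not show that the cell expresses an abundant gene. Every difference after thinning had the same sign in 4 of 4 mice, and an exact two-sided sign-flip permutation test gave p = 0.13 for each, the smallest that 4 mice allow, with the same value after adjustment over the 6 markers.

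Putative spiral ganglion neurons stood out by immediate early and dissociation genes. Fosb, an activity-induced transcription factor gene, stood at 261 ± 32.3 CPM (SD, n = 4) against 61.1 to 64.5 in the type I subtypes (log2 difference 1.76 ± 0.09 from the mean of all other populations). Fosl2 (1.69 ± 0.20), the nuclear receptor gene Nr4a2 (1.57 ± 0.26) and Klf4 (1.52 ± 0.11) were higher as well. Npy, a neuropeptide gene, reached 223 ± 48.9 CPM in putative and 295 ± 129 in type II neurons against 3.11 to 3.34 in type I (4.58 ± 0.17), and H2-Q6, a histocompatibility gene, was higher by 4.05 ± 0.44. Cells with 3 or more Fabp7 UMIs held 979 Npy UMIs in putative neurons, and the other putative cells 34. In type II, cells with under 3 Fabp7 UMIs held 2 Npy UMIs among those with Prph and 1 among those without. Lhcgr, the receptor of luteinizing hormone, had 30 UMIs in putative and 10 in type II neurons and none in type I. Without cells of 3 or more Fabp7 UMIs Lhcgr did not pass the low-count filter. Runx2, Nkx6-1, Zic5, Rgs1, Slc22a2 and Prrx1, the other genes ranked highest, stood at 5.00 to 8.23 CPM in putative neurons, at 0.383 to 1.53 CPM in type I and at 0 UMIs in type II, and Rgs1 lost its call without mouse 4 (adjusted p = 0.0874).

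The immediate early and dissociation list rose, with 26 of 32 genes higher and none lower (28 adjusted over the list alone; median 1.04), and held with an estimated correlation (adjusted p = 4.89e-70, and 0.000389 with an estimated correlation). Transcription factor genes rose in 26 of 65 cases and fell in 6 (28 and 7 adjusted over the list alone), a call that also held with all cells (adjusted p = 3.24e-06, and 0.0251 with an estimated correlation). They include Ebf2 (2.43 ± 0.50), Nfix (1.55 ± 0.16) and the Notch target Hes1 (1.45 ± 0.12). Without cells of 3 or more Fabp7 UMIs camera gave that list adjusted p = 0.00084, but 0.132 with an estimated correlation. Hes1 then stood at 0.76, Nfix at 1.45 and Ebf2 at 2.43. Axonal injury response genes were higher in 4 of 11 cases and lower in 1 (4 and 2 adjusted over the list alone). Atf3, the classic injury factor, was higher by 1.16 ± 0.07, Jun by 0.79 ± 0.06 and Gadd45a by 0.79 ± 0.12 (camera adjusted p = 2.44e-05, and adjusted p = 0.143 with an estimated correlation). Atf3 and Jun are also on the immediate early and dissociation list. The remaining higher gene was Npy, at 2616 CPM in putative cells with 3 or more Fabp7 UMIs and 8.63 CPM in the rest. With type I alone as the comparison Gadd45a stood at 1.12, since it was also high in type II. Glial transcripts were higher in 3 of 19 cases, also adjusted over the list alone, with Apoe at 2.17 ± 0.08 (camera adjusted p = 0.00605, and adjusted p = 0.214 with an estimated correlation). Mitochondrially encoded genes were higher in 10 of 13 cases (13 adjusted over the list alone), such as mt-Nd6 (0.56 ± 0.11) and mt-Nd3 (0.38 ± 0.07), at camera adjusted p = 8.62e-07, and adjusted p = 0.275 with an estimated correlation. Against type I alone, a comparison added after seeing the data that leaves out the low values of type II, 3 of 13 were higher (median 0.14, camera adjusted p = 0.0404, and adjusted p = 0.625 with an estimated correlation), with mt-Nd3 at 0.18.

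Genes of neuronal structure and release were lower. Of 39 axonal cytoskeleton genes 11 were lower and none higher (17 adjusted over the list alone), with the stathmin genes Stmn4 (-0.78 ± 0.12) and Stmn2 (-0.63 ± 0.09), at camera adjusted p = 1.41e-09, and adjusted p = 0.0585 with an estimated correlation. Synaptic vesicle and release genes were lower in 11 of 45 cases and higher in 1 (15 and 2 adjusted over the list alone), including Syngr3 (-0.69 ± 0.13) and Vamp2 (-0.55 ± 0.11), at camera adjusted p = 0.000438, and adjusted p = 0.355 with an estimated correlation. Oxidative phosphorylation genes were lower in 9 of 76 cases (1 adjusted over the list alone), for example Ndufv3 (-0.28 ± 0.07), at camera adjusted p = 1.35e-13, and adjusted p = 0.368 with an estimated correlation. The mean of the others includes type II, where these genes are low, and against type I alone 70 of 76 were lower (median -0.27, camera adjusted p = 1.67e-29, and adjusted p = 0.214 with an estimated correlation). Against type I alone 26 cytoskeleton genes were lower and 1 higher, and 22 synaptic vesicle and release genes lower and 5 higher, but the differences of Stmn4 (-0.51), Stmn2 (-0.29), Syngr3 (-0.46) and Uchl1 (-0.33) were smaller, since these genes are high in type II. Uchl1 (-0.63 ± 0.07) and the RNA-binding protein gene Elavl4 (-0.24 ± 0.06) were lower, and of the 16 general neuron markers 4 were lower and none higher. Igsf21 (-1.04 ± 0.19), Gata3 (-0.93 ± 0.14), Tbc1d8 (-0.84 ± 0.15) and Ergic1 (-0.83 ± 0.18) were among the 10 genes ranked lowest. The other 6 lost their calls without single mice. These were Lingo3 without mouse 1, 3 or 4 (adjusted p = 0.0837 to 0.0949), Fgd2 without 2 or 3 (0.187 and 0.126), Pnma2 without 3 (0.0863), Shisa8 without 1, 3 or 4 (0.0705 to 0.0969), Txnl4b without 2 (0.117) and Jph4 without 2 or 4 (0.0706 and 0.0653). All 4 type IC markers were higher, such as Lypd1 at 1024 ± 180 CPM (1.23 ± 0.21), and so were 2 of 3 type IB markers, Ttn (1.90 ± 0.27) and Calb1 (0.78 ± 0.22, with adjusted p = 0.0744 without mouse 2 and 0.0637 without mouse 3). The others enter as a mean of log levels, which populations low in a marker pull down. Per mouse Lypd1 stood at 822 to 1260 CPM in putative neurons and 2654 to 3190 in type IC. Calb1 stood at 12.5 to 22.6 CPM, against 59.3 to 72.5 in type IB. Neither reached the level of the subtype it marks.

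In putative neurons edgeR called 1793 genes, 1329 higher (74.1%) and 464 lower, 706 of them by at least 2-fold. Their cells were the shallowest, with a median of 2384 genes detected, and they carried more markers of other cell types. The satellite glia sum was 8155 ± 433 CPM against 1268 to 1349 in type I, and 19.0% ± 2.67 of the cells held 3 or more Fabp7 UMIs. Fibroblast markers summed to 389.8 ± 152 CPM against 106 to 111 in type I, endothelial markers to 196 ± 63.6 against 71.2 to 76.5, chondrocyte-like markers to 123 ± 32.7 against 32.9 to 34.8 and supporting cell markers to 201 ± 13.5 against 99.3 to 112. Pericyte markers summed to 75.7 ± 34.8 CPM against 26.2 to 32.4, and oligodendrocyte markers to 81.8 ± 26.0 against 36.4 to 40.2. Without cells of 3 or more Fabp7 UMIs Fabp7 stood at -0.16 (3.90 ± 0.17 with all cells), Npy at 1.496 and Apoe at 0.88, the glial list gave adjusted p = 0.864, and axon guidance was called up (adjusted p = 0.0456, and 0.323 with an estimated correlation). The count was 1146 without mouse 2, 1186 in cells above the median depth (without the type II sum of mouse 2, which had 7 cells) and 223 with the same number of cells in every sum. Against type I alone 3057 genes were called, 1854 higher and 1203 lower, and 1572 were shared with the comparison above in the same direction. These were 1247 of its 1329 higher and 325 of its 464 lower calls, 18 calls reversed, and 29 of the 32 immediate early and dissociation genes were higher. Gata3 (-0.18), Vamp2 (-0.03), Shisa8 (-0.07), Igsf21 (-0.36) and Calb1 (0.36) were then not called.

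**Figure D3:**
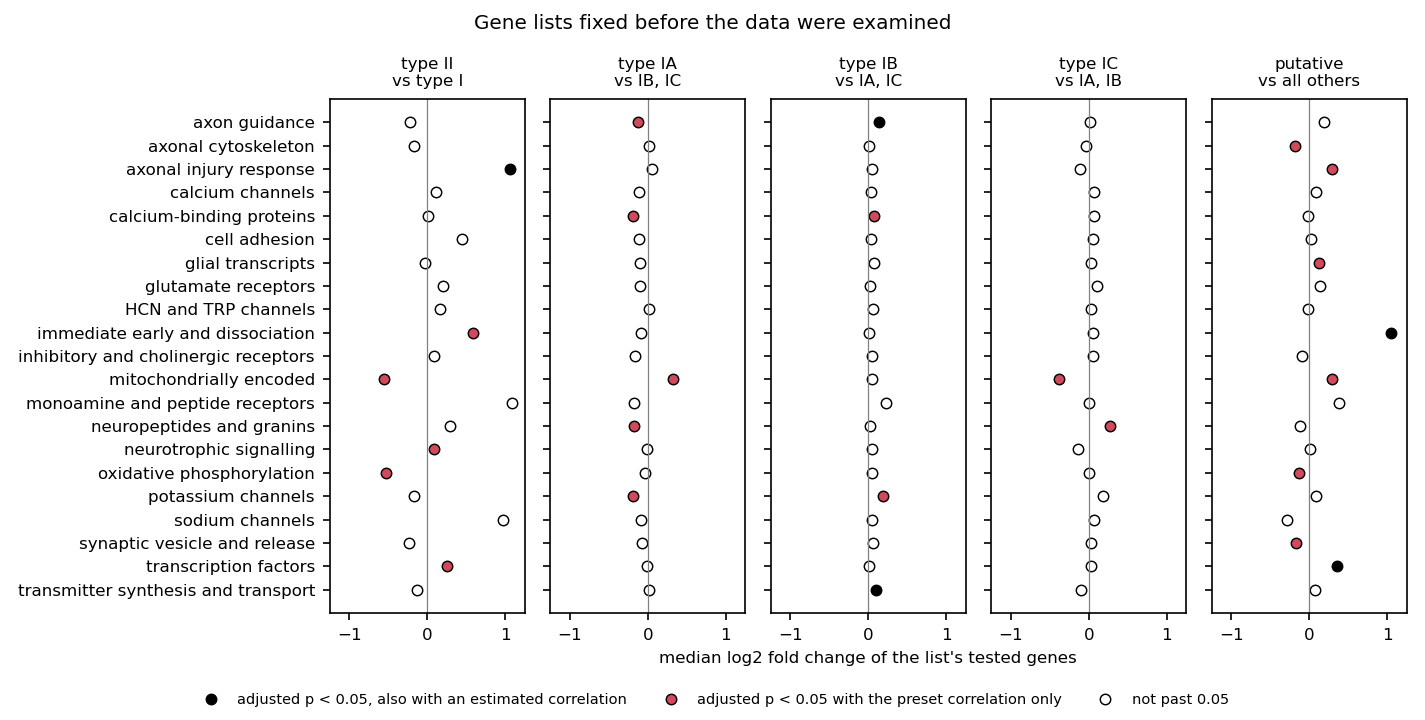
Median log2 difference of the tested genes of 21 function lists in the 5 comparisons. Red symbols are camera calls with the preset correlation only, black symbols calls that hold with an estimated correlation, such as axonal injury response in type II at 1.06, and open symbols lists not called.

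With the preset correlation camera called 6 lists in type II, 5 in type IA, 4 in type IB, 2 in type IC and 8 in putative neurons. With an estimated correlation and all cells the calls that held were axonal injury response in type II, axon guidance and transmitter synthesis and transport in type IB, and immediate early and dissociation genes and transcription factors in putative neurons. With all cells some lists were called in no comparison. In type II these were calcium channels (4 higher and 2 lower of 18, adjusted p = 0.44), cell adhesion (29 and 14 of 72, 0.0635), glutamate receptors (8 and 5 of 19, 0.44), monoamine and peptide receptors (4 and 2 of 12, 0.507), inhibitory and cholinergic receptors (1 and 2 of 9, 0.861), sodium channels, and HCN and TRP channels (5 and 6 of 17, 0.507). In every called list the median, the mean and the test had 1 sign. They differed in sign in 7 lists in type II, which were axon guidance, axonal cytoskeleton, glial transcripts, HCN and TRP channels, potassium channels, synaptic vesicle and release, and transmitter synthesis and transport. In type IA this held for 6 lists, in type IB for 4, in type IC for 5 and in putative neurons for 6, among them calcium channels in all 4 and HCN and TRP channels in all but type IB. Schwann cell markers summed to 3347 to 3753 CPM in the 5 populations, macrophage markers to 64.9 to 70.5 and erythrocyte markers to 825 to 1035. The hair cell sum of 2817 to 5662 CPM was almost all Calm2 (2809 to 5659 CPM), a calmodulin gene that neurons express.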

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

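The tests on satellite glia transcripts, on type II cells without Prph and on nuclear respiratory chain genes were chosen only after the results they measure had been seen, and the test of depth was planned. The samples form 1 group of mice, so no biological explanation was tested.

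Satellite glia transcripts in type II and putative neurons stood out because Fabp7 and Apoe were high in part of the cells of both populations. Free RNA in all droplets is argued against, since the share of cells with 3 or more Fabp7 UMIs was 16.0 times that in type I in the mouse and population where the ratio was lowest. Transcription in type II neurons cannot be told apart, since the type II cells with Prph that held Apoe at 1.46 ± 0.388 times the type I level (SD, n = 4) were chosen for having under 3 Fabp7 UMIs. In cells with 3 or more Fabp7 UMIs the excess of Apoe, Ednrb and Npy per Fabp7 UMI differed between the populations by at most 1.08 times, so a candidate explanation is RNA of satellite glia joined to part of the cells. Putative cells with 3 or more Fabp7 UMIs held Apoe at 62749 CPM and type II cells with Prph and Fabp7 at 22804, against 951 in type I.

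Type II cells without a Prph UMI numbered 37 of 95. Shallow sampling is argued against, since 1 common Prph rate gives 4.64 such cells, and the count was 7.98 times that. A classifier on 1 part of the UMIs labelled 78.4% of them type I, against 1 of 58 cells with Prph. Of those with under 3 Fabp7 UMIs it labelled 86.2% type I. On the other part of the UMIs the sum of 379 type II genes was taken in type II cells with under 3 Fabp7 UMIs. In those without Prph it lay 43.0% of the way from type I (2289 CPM) to those with Prph (34344 CPM). The 379 genes were picked from the type II comparison on all UMIs, which held these same cells. This draws the position away from type I. The presence of type I cells in the type II population cannot be told apart from other mixtures. The position and the share over all 37 cells lie between the bounds set, while 86.2% is past the bound for type I cells. Type I cells may account for part of the 37.

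The share of mitochondrial UMIs was higher in type IA than in type IC, at 12.8% ± 0.894 and 8.76% ± 0.297 of UMIs (means over cells, SD over 4 mice). Depth as the whole cause is argued against, since within 5 bins of UMIs per cell in each mouse 80.4% ± 8.72 of the difference was left (3.22 of 4.05 points). In the bin of each mouse where it was smallest the difference was 1.03 ± 0.26 points (0.834 to 1.39), so its size varied between bins. A general rise of respiratory chain transcripts is argued against too, since the median of nuclear oxidative phosphorylation genes was -7.86% ± 12.9 of the mitochondrially encoded one (-0.04 against 0.46 on the log2 scale). What sets the share stays open, and leakage of cytoplasmic RNA from cells was not tested.

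In 19 of 286 groups of 4 mice 1 mouse lay far from the others, where chance gives about 1 in 20 groups. Mouse 4 was that mouse 7 times, mice 1 and 2 each 5 times and mouse 3 2 times. In type II, mouse 4 had a log2 difference of 0.37 for Slc17a6 (others 1.20 to 1.37), -1.52 for mt-Nd1 (-0.53 to -0.43) and -2.85 for Zfp958 (-3.16 to -3.11, values set by the prior count, since Zfp958 had 0 UMIs in type II), with Slc17a6 at 123 CPM (218 to 228) and Calca at 68.2 CPM (14.6 to 20.5). Th was seen in 13.04% of the type II cells of mouse 1 (36.4% to 38.5% in the others). In type IA the values were 4.52 for Tmem132c in mouse 4 (3.78 to 3.87), -1.70 for Edn2 in mouse 1 (-2.53 to -2.41), -1.73 for Nalcn in mouse 3 (-2.60 to -2.47), 3936 CPM for Snap25 in mouse 2 (4170 to 4198) and 1.17% of cells with 3 or more Fabp7 UMIs in mouse 1 (0.381% to 0.496%). In type IB they were 1.23 for Casz1 in mouse 4 (0.93 to 0.98) and -0.74 for Ebf1 in mouse 1 (-0.84 to -0.82). In type IC they were 3.70 for Chst9 in mouse 2 (4.19 to 4.28), 4.22 for Ccdc109b in mouse 2 (3.78 to 3.82) and -3.26 for Fmnl1 in mouse 3 (-1.98 to -1.75). In putative neurons they were 4.01 for Slc22a2 in mouse 1 (1.61 to 1.71, in part set by the prior count, since type II had 0 UMIs), -0.42 for Lingo3 in mouse 2 (-2.60 to -2.42, from 2 UMIs in all putative neurons) and 296 CPM for Npy in mouse 2 (195 to 204).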

How the results depend on the processing

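Leaving out cells with 3 or more Fabp7 UMIs, leaving out type II cells lacking Prph, and comparing putative neurons with type I alone were added after seeing the data. The 201 pairs of a gene and a comparison that were followed gave 2565 values under the alternatives. Of these 2401 kept direction and call, 162 kept direction and lost the call, and 2 reversed. The reversed ones were Slc17a6 in type II with labels from a part of the UMIs (-0.12) and Fabp7 in putative neurons (-0.16) without cells of 3 or more Fabp7 UMIs. Many followed genes were named for passing the threshold with 1 direction in every mouse, so kept directions were in part fixed by that choice. Pairs whose gene failed a filter gave no value, and with the same number of cells only 93 remained. Over all main calls still tested there, 230 reversed in type IA, 34 in IB, 196 in IC, 31 in putative neurons and 0 in type II. With rebuilt labels 67 reversed in type II. Size factors of DESeq2 and no low-count filter ended no call of a followed gene, and leaving out a mouse ended 8 to 17. Gene counts for type II, IA, IB, IC and putative neurons fell to 1563, 176, 23, 162 and 223 with the same number of cells in every sum, where only 4835 genes were tested. In cells above the median UMIs they were 1659 for type II, 502 for type IB and 1186 for putative neurons, in a fit that also lacked the type II sum of mouse 2 (7 cells). Type II gave 1914 without cells of 3 or more Fabp7 UMIs, and putative neurons 3057 against type I alone. Without the mouse block type IA gave 2071, type IB 333 and type IC 1723, the type II and putative counts stayed within 1.5 times, and 9 of the 201 calls were lost. Leaving out a mouse gave 506 to 745 in type IB and 1146 to 1691 in putative neurons. With an estimated correlation 1 list was called in type II, 0 in type IA, 2 in type IB, 0 in type IC and 2 in putative neurons. Fry, which tests a list against no change, called 15 in type II, 13 in type IA and 13 in type IC. Without the block 11 lists were called in type II and 6 in type IC. Leaving out a mouse gave 7 to 10 lists in type II (10 without mouse 2) and 2 to 6 in type IC (6 without mouse 4). With putative cells out of the denominator type IA took 38.1%, type IB 26.3% and type IC 34.0%. Apart from fewer genes or cells by construction, the cause was not tested. The alternatives for neurons against non-neuronal cells (a filter on glial marker genes, a minimum of UMIs per cell, another cluster resolution) were not run, since the comparison was not analysed here. Of simulated 2-fold changes 55.2% were recovered for type II, the lowest share. The simulation gave all populations the same means and dispersions, so only the size of the sums, the contrast and the genes drawn differed. Sums held 131668 to 546679 UMIs in type II, 717528 to 1602700 in putative neurons and 3830864 to 10156321 in type I subtypes. The part of each in the recovery was not tested. Far fewer genes were changed in the simulation than were called in the data. Depth left 237 of the 505 putative cells too shallow for the marker shares.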

Other observations

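Tac1, the gene of substance P, was singled out after its values were seen, and it did not pass the low-count filter. Its 215 UMIs in type II lay almost all in 5 cells, which held 211 of them (4, 40, 24, 16 and 127 per cell) and came from mice 1, 3, 3, 4 and 4. None of the 5 cells had a Dupd1 UMI, and the last had 103 Prph UMIs, 20.7% of all Prph UMIs in type II. Tac1 lies on chromosome 6 (7554879 to 7565834, plus strand).

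The tests on the place of type IB were planned before their results were seen. On UMIs not used for the labels, of 550 genes that differ between types IA and IC, type IB lay between them in 77.9% ± 3.27 (SD, n = 4 mice). For type IA the same share was 35.5% of 212 genes that differ between the other subtypes, and for type IC 36.8% of 281. An intermediate type IB needs this, so type IB may lie between the others in most of the genes that set them apart. Single cells, labelled by the classifier, were also placed on a scale from the mean type IA to the mean type IC cell. The SD of type IB cells was 0.935 times that of the other subtypes (highest mouse 1.14), with a mean position of 0.539 ± 0.0122. This cannot exclude a mixture of type IA and type IC cells. Cells close to either subtype would have been labelled as that subtype, and droplets holding a cell of each would also lie near the middle.

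Labels of the sums were also exchanged within mice, in 30 splits per comparison with the real one included. In each comparison 1 of the 30 splits, the real one, gave as many genes. The labels come from the UMIs that are compared, so the real ones were bound to give more genes, and the splits cannot exclude chance. The real and the highest other counts were 3088 and 1143 in type II, 3709 and 168 in type IA, 823 and 208 in type IB, 3389 and 2451 in type IC, and 1793 and 3 in putative neurons. The highest other splits for type II and type IC gave that label to the type IA sums in all 4 mice, so their counts reflect the structure that type IA differs from the rest.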
